A study of Homo sapiens with 16 samples.

How the data were processed

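Total RNA of co-cultured human cancer cells and mouse stromal cells was hybridised to single-colour Illumina mouse-6 v1.1 BeadChips, 1 array per sample. The 16 samples form 4 groups of 4: MDA-MB-231, a human breast carcinoma line, with mouse astrocytes; MDA-MB-231 with mouse fibroblasts; PC14, a human lung carcinoma line, with astrocytes; and PC14 with fibroblasts. Groups and replicate numbers come from the sample titles, which match the source names. The protocol field gives the first of these pairings for all 16 samples and was not used, and the organism field names human although the arrays carry mouse probes. The series design pairs these hybridisations with human arrays, which were not used here. The labels do not say that the replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

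The authors exported bead signals with BeadStudio, per the submitters' processing notes, with no version given in the sources used here. The deposited signal table holds linear intensity values for 46628 probes on all 16 arrays, with no detection p-values. It is not normalised: array medians differ, and no value is negative. The second table, the series matrix, holds log2 values that the authors made: taking log2 of the signals and then quantile normalising gave the same 746048 values within 0.001, with a largest difference of 5e-04. Its column medians lay between 5.988 and 5.9885, it is not centred per probe, and it served as an alternative.

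From the signals, the background was corrected with limma's normexp (offset 50), arrays were quantile normalised, and log2 was taken (limma 3.58.1, R 4.3.3). The 43 control probes (spike-ins, bacterial genes and primers) were left out after that, which left 46585 features. One limma model (lmFit and eBayes, 4 group means, 12 residual and 6.46 prior degrees of freedom) gave 5 contrasts: astrocyte minus fibroblast partner with each tumour line, MDA-MB-231 minus PC14 with each partner, and the interaction. A feature was called at a Benjamini-Hochberg adjusted p under 0.05 over all features. A second count also asked for an absolute log2 difference of at least 1 (2-fold). Errors of log2 differences are standard errors from that model, and errors of group means are SDs over 4 arrays. The number of arrays limits the precision. On simulated data with the real means and spreads of the 46585 features, limma recovered 73 of 100 features changed 1.41-fold and 100 of 100 changed 2-fold for the astrocyte minus fibroblast contrast with MDA-MB-231, with 6 false calls. For the interaction it recovered 44 of 100 and 90 of 100, with 10 false calls. The changed features were drawn from those with a mean above the median, and no other feature differed between groups. Noise was normal and independent, so these figures do not give the power or error rate on the real data.

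The files identify features by probe identifier and do not pair these with gene symbols; a number within an identifier is used here only to order probes of one transcript. The gene table used here is of the human genome (GRCh38.p14), and none of the genes on the 18 planned mouse gene lists could be matched (0 matches), so those lists, including the astrocyte and fibroblast markers, were not analysed here. The contrasts, thresholds, normalization, first set of alternatives and rule for named features were chosen before the data were examined. The rule took, per contrast, the 6 largest positive and 6 largest negative log2 differences among features that were called, had a gene symbol and did not overlap between the 4 and 4 arrays (for the interaction, called alone). It was applied to probes whose identifier itself says what they measure. These are 13 mitochondrial genes, 4 ribosomal RNA probes, 3 SV40 probes, 1 CDKN2A p16 probe, 3 retroviral probes, 9 probes with a RefSeq accession, 27 vector, tag and reporter probes, 300 immunoglobulin and 52 T-cell receptor probes. These classes, and the naming of other members of them, were chosen after the data were seen. The design also restricted tests to features with a gene name where no detection p-value exists; every feature except the controls was tested in its place. Of features with an identifier alone, at most 2 per direction and contrast are given, those with the largest differences among called features whose arrays do not overlap.

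A background limit was set per array after the data were seen, as the 99th percentile of the raw signal of the 352 immunoglobulin and T-cell receptor probes. It served to describe features and to set bounds, not to filter the main tests. Where a probe was not above background on any array of the dimmer group, the difference is given as at least N-fold: the brighter group's mean against the mean of, per array, the higher of the lowest normalised signal above background and the probe's own signal. All folds are on the normalised scale with the offset, which understates changes of dim probes.

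The alternatives chosen at the start were cyclic loess, median scaling and no between-array normalization, the authors' log2 values, no background correction, an offset of 16, a filter on features with a mean above the median, a fit of only the groups compared, a trended robust eBayes, array weights, the replicate number as a block, and leaving out each array. After the data were seen, a fit on the arrays numbered 1 to 3 and a filter on features above background on at least 4 arrays were added. The files name no slide or scan, so no slide block was fitted.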

Results

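Genome-wide mouse probe signals were measured in co-cultures of human cancer cells with mouse astrocytes, the main supporting glia of the brain, or with NIH 3T3 mouse fibroblasts, a connective tissue line. The series design aims the mouse arrays at the stromal cells' transcripts, while the RNA on each array came from both species. The median raw signal per array was 69.33 ± 5.95 for MDA-MB-231 with astrocytes and 68.8 ± 7.80 with fibroblasts (SD, n = 4 each), against 58.78 ± 7.05 and 59.2 ± 9.38 for PC14. Between 11650 and 15166 features per array lay above background, and 9851 did so on all 16 arrays. Arrays numbered 4 had the highest median signal in each group. Correlations between arrays, across features, were 0.99 to 0.9952 within groups and 0.929 to 0.981 between groups.

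**Figure D1:**
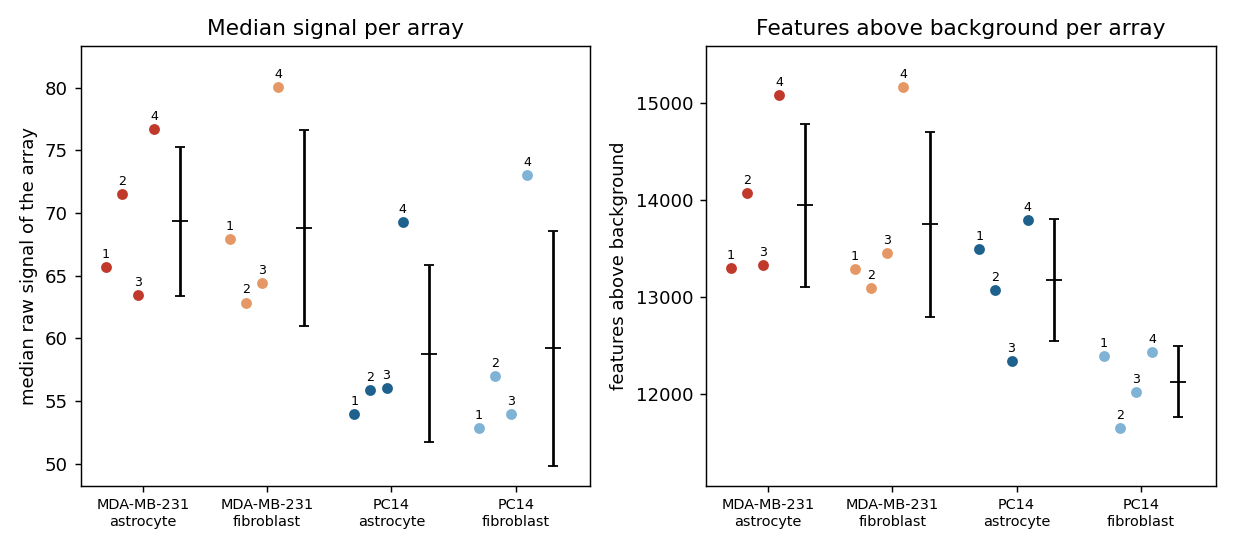
Median raw signal (left) and number of features above background (right) of each of the 16 arrays, by group; the small digit is the replicate number and the bars are mean ± SD of 4 arrays. The array numbered 4 has the highest median signal in each group, from 69.25 to 80.06.

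The first comparison asks which mouse array signals differ between astrocyte and fibroblast partners of MDA-MB-231 cells. SV40 large T antigen, a viral oncoprotein often used to immortalise cells, was detected with astrocytes (raw signal 229 ± 44.5, SD, n = 4) and lay at background on all 4 fibroblast arrays (58.32 ± 2.58). It was at least 2.05-fold higher with astrocytes (fitted log2 difference 1.67, SE 0.10, limma adjusted p = 7.69e-11), and the probe common to large T and small t antigen was at least 1.69-fold higher (adjusted p = 2.55e-09). Of the 9 probes with a RefSeq accession, 4 rose and 1 fell: NM_013556.1 was higher with astrocytes by 1.38 (SE 0.11, adjusted p = 2.84e-09), NM_007393.1 by 0.93, NM_009735.2 by 0.64 and the second probe of NM_019639.2 by 0.37 on the log2 scale. The last of these calls ended under median scaling (0.33, adjusted p = 0.212; adjusted p 0.353 without between-array normalization). The first probe of NM_019639.2 was not called in this or any other contrast (log2 means here 14.569 with astrocytes and 14.405 with fibroblasts). Its raw group means, 23730 to 26460, lay near the array maxima, where a difference may not show. NM_009438.3 was lower (log2 -0.29, adjusted p = 0.0167), a call that ended without replicates 3 or 4 of the astrocyte arrays or 1 or 2 of the fibroblast arrays (adjusted p 0.0543 to 0.0724) and under median scaling (adjusted p = 0.467).

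All 3 retroviral probes were also somewhat higher with astrocytes than with fibroblasts in the MDA-MB-231 co-cultures. The 3′ long terminal repeat (LTR) of Moloney murine leukaemia virus (MoMuLV) differed by 0.51 (SE 0.10, adjusted p = 0.000711), the 5′ LTR of Moloney murine sarcoma virus (MoMuSV) by 0.42 (SE 0.08) and the extended packaging signal by 0.48 (SE 0.09). LTRs hold the promoter and the polyadenylation signal of a retrovirus, and these are carried by many gene transfer vectors. Under cyclic loess both LTR calls ended (0.35, adjusted p = 0.0796, and 0.20, adjusted p = 0.457), and that of the 3′ LTR also without between-array normalization (0.40, adjusted p = 0.099). Limma called none of the 27 vector, tag and reporter probes (0 at an unadjusted p under 0.05) and none of the 13 mitochondrial probes (3 at an unadjusted p under 0.05). Some mitochondrial probes lay near the array maxima (29874 to 38415), where a difference may not show in this or any other contrast. Among them were ND4 and CytB, with raw group means from 27330 to 32620. The ND6 probe lay at background on all arrays. One of the 4 ribosomal RNA probes, the last of 3 18S probes in the order of the numbers in their identifiers, was lower (log2 -0.30, adjusted p = 0.0202), and that call ended without replicate 3 of the astrocyte arrays or replicates 1 or 3 of the fibroblast arrays (adjusted p 0.0682 to 0.0909) and under median scaling (adjusted p = 0.158). The remaining probes named by the rule, immunoglobulin segments IGHV1S129 and IGKV9-123, were called lower but lay below background on all 16 arrays, so no fold is given. Their calls ended without replicates 2, 3 or 4 of the astrocyte and 1, 3 or 4 of the fibroblast arrays for the first (adjusted p 0.0606 to 0.108), and 2 or 4 and 1, 2 or 3 for the second (adjusted p 0.0797 to 0.117).

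In all, 10333 of 46585 features were called, 5310 higher and 5023 lower with astrocytes, and 1995 of them differed at least 2-fold (1000 higher, 995 lower). Of these, 518 differed at least 4-fold and 68 at least 16-fold. Among features with no name in the files, scl43662.2_474-S rose from background to a log2 signal of 12.38 ± 0.08 with astrocytes (at least 54-fold), and scl072362.1_11-S was at least 32.4-fold higher. The features scl39570.9.1_4-S and scl42790.6_48-S went the other way, at background with astrocytes and at 13.23 ± 0.09 and 13.52 ± 0.11 with fibroblasts (at least 98.7-fold and 121-fold lower with astrocytes).

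The same comparison with PC14 cells showed a larger SV40 signal. Large T antigen reached a raw signal of 915 ± 242 with astrocytes and lay at background with fibroblasts (51 ± 10.8), so that it was at least 10.3-fold higher (fitted log2 difference 4.19, SE 0.10, limma adjusted p = 4.52e-17). The common large T and small t probe was at least 7.12-fold higher (adjusted p = 3.86e-16). The small t probe differed by 0.49 (SE 0.11, adjusted p = 0.00255) but was above background on only 1 of the 8 arrays. NM_009735.2 rose by 1.43 (SE 0.09), NM_013556.1 by 1.001 (SE 0.11), the second probe of NM_019639.2 by 0.74 (adjusted p = 0.0552 without between-array normalization, which ended its call) and NM_007393.1 by 0.68, while NM_009438.3 fell by 0.96 (SE 0.09, adjusted p = 2.63e-08).

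The 3 retroviral probes lay at background on all 8 PC14 arrays and were not called between partners by limma (0 at an unadjusted p under 0.05). Neither eGFP (enhanced green fluorescent protein, a reporter) nor NeoR (neomycin resistance, a selection marker), nor any other of the 27 vector, tag and reporter probes, was called (0 at an unadjusted p under 0.05). Of the 13 mitochondrial probes only ND1, a subunit of respiratory complex I, was called (log2 -0.32, SE 0.10, adjusted p = 0.0276). That call ended without replicates 2 or 3 of the astrocyte arrays or 2, 3 or 4 of the fibroblast arrays (adjusted p 0.0503 to 0.0823), and also under cyclic loess (adjusted p = 0.158). The other probes named by the rule were the immune receptor segments IGKV1-99, TRAV5-1, TRBV12-2 and TRGV4, called lower with astrocytes, of which TRAV5-1 and TRGV4 lay below background on all 16 arrays. The TRAV5-1 call ended without replicate 3 of the astrocyte or 1 of the fibroblast arrays (adjusted p = 0.0588 and 0.0612), and the TRBV12-2 call without replicate 1 of the astrocyte or 1 or 3 of the fibroblast arrays (adjusted p 0.0667 to 0.102). The calls of IGKV1-99, TRBV12-2 and TRGV4 ended without between-array normalization (adjusted p = 0.948, 0.795 and 0.23).

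With PC14, 9477 features were called, 4632 higher and 4845 lower with astrocytes, and 1756 differed at least 2-fold (1038 higher, 718 lower). Median scaling called 6059 features, 3936 higher and 2123 lower, and no between-array normalization 4727, 3162 higher and 1565 lower. RIKEN clone B230326M24 was at least 51-fold higher with astrocytes and scl32592.2.658_11-S at least 35.5-fold. The features scl39570.9.1_4-S and scl42790.6_48-S were again at background with astrocytes, at least 121-fold and 90.5-fold lower.

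The astrocyte minus fibroblast differences were shared in part between the tumour lines. At 2-fold, 610 features were higher and 479 lower with astrocytes in both, and 10 were called in opposite directions. Independent lists of these sizes over all 46585 features would share 22.28 and 15.34. Every 2-fold call lay among features above background on at least 4 arrays, so these expected numbers are too low. Among all calls, 2865 were higher and 2829 lower in both and 582 opposite. Without between-array normalization 1913 were higher and 1118 lower in both. The contrasts share no array. The log2 differences correlated across features with Pearson's r = 0.75 and Spearman's rho = 0.419, and with r = 0.764 over features above background on at least 4 arrays; features are not independent replicates.

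**Figure D2:**
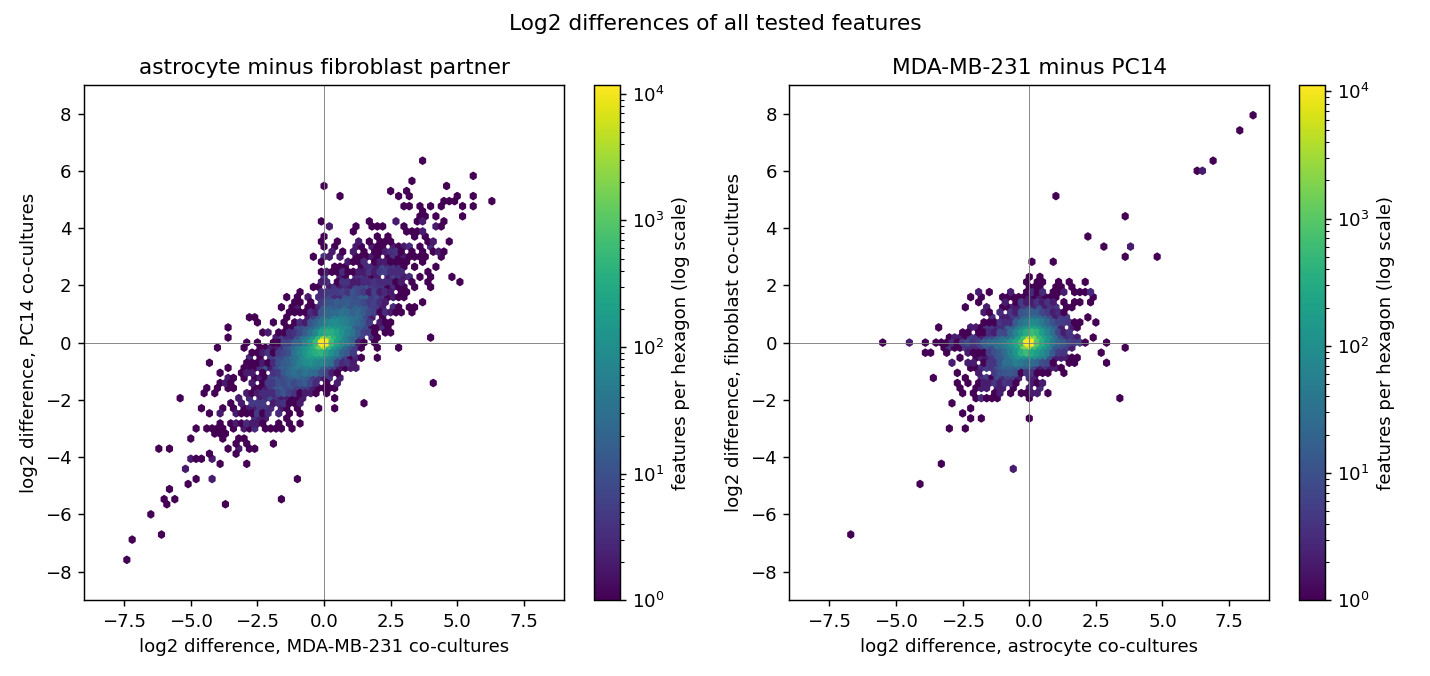
Log2 differences of all 46585 features, as hexagons coloured by the number of features (log scale). Left, astrocyte minus fibroblast partner with MDA-MB-231 (x) and PC14 (y), with r = 0.75; right, MDA-MB-231 minus PC14 with astrocytes (x) and fibroblasts (y), with r = 0.355. The most positive points on the right are the LTR probes, at 7.96 and 8.40 with astrocytes.

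The tumour lines were then compared within the astrocyte co-cultures. The retroviral LTR probes differed most: the 3′ MoMuLV LTR had a raw signal of 18000 ± 3378 and the 5′ MoMuSV LTR of 23330 ± 723 with MDA-MB-231, and both lay at background on all 4 PC14 arrays (50.71 ± 6.62 and 51.16 ± 6.26). They were at least 156-fold and 213-fold higher with MDA-MB-231 (limma adjusted p = 3.21e-20 and 2.25e-22). The packaging signal was at least 1.66-fold higher (adjusted p = 5.79e-10). NeoR was higher with MDA-MB-231 (6413 ± 1053 against 1987 ± 370, log2 difference 1.07, SE 0.10) and eGFP was lower (2747 ± 1024 against 9246 ± 2299, log2 difference -2.54, SE 0.21). The third vector probe called, HSV1 thymidine kinase (0.15), lay below background on all arrays, and its call ended without replicates 3 or 4 of the MDA-MB-231 or 2 or 3 of the PC14 arrays (adjusted p 0.0992 to 0.119). SV40 large T antigen was lower with MDA-MB-231 (log2 difference -2.51, SE 0.10, adjusted p = 5.79e-13), as was the common probe (-2.26). The small t probe was called too (-0.43, adjusted p = 0.0101), but it lay above background on only 1 of the 8 arrays, and its call ended without between-array normalization (adjusted p = 0.0891).

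Of the ribosomal RNA probes, the last 18S probe was lower with MDA-MB-231 (log2 -1.74, SE 0.09, limma adjusted p = 3.25e-11). The middle 18S probe differed by -0.54 (adjusted p = 0.0121, and 0.012 as the difference under median scaling). The first 18S probe was not called, nor was the 28S probe, which lay at background on all arrays. Of the 13 mitochondrial probes, 4 were called lower: ND5 (-0.46), ND2 (-0.35), ATP6 (-0.32) and COXII (-0.30). All 4 calls ended without replicate 1 or 2 of either astrocyte group (adjusted p 0.0527 to 0.163), and ND2 (0.246) and ND5 (0.045) changed sign under median scaling. The ATP6 and COXII calls also ended without replicate 3 of either group (adjusted p 0.0561 to 0.0975), and the ND2 call without replicate 3 of MDA-MB-231 or 4 of PC14 with astrocytes or replicate 2 of either fibroblast group (adjusted p 0.0519 to 0.102). As a set the 13 probes were not called by camera (adjusted p = 0.168; adjusted p = 0.941 with an estimated correlation), and camera called no class among the mitochondrial, immunoglobulin and T-cell receptor probes in any contrast. Differences of mitochondrial probes near the array maxima may not show in this test either. Of the RefSeq probes, NM_009735.2 was lower (-1.12, SE 0.09) and NM_009438.3 (0.45) and NM_013551.1 (0.73) were higher with MDA-MB-231. The second probe of NM_019639.2 was lower (-0.42), and its sign turned under median scaling (0.099).

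Between the lines with astrocytes, 8142 features were called, 4288 higher and 3854 lower with MDA-MB-231, and 767 differed at least 2-fold (226 higher, 541 lower). The split depended on the scaling, and the MDA-MB-231 groups had the higher mean of median raw signals. Median scaling gave 7086 higher and 1783 lower (at 2-fold 1388 features, 1107 higher), and no between-array normalization gave 9353 and 889 (at 2-fold 1818 features, 1571 higher), with the median of all features shifted by 0.111. GI_6715563-S was lower with MDA-MB-231 (log2 signal 7.79 ± 0.28 against 14.58 ± 0.07), and scl24120.2_589-S was at least 34.7-fold lower. The features scl27604.2_9-S and scl00280287.2_244-S were at least 18.8-fold and 8.71-fold higher.

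In the fibroblast co-cultures the same vector probes separated the tumour lines. With MDA-MB-231 the 3′ MoMuLV LTR (13820 ± 3400) and the 5′ MoMuSV LTR (19760 ± 2490) were at least 99.9-fold and 145-fold higher than with PC14 (limma adjusted p = 1.11e-19 and 5.81e-22), and the packaging signal at least 1.09-fold. NeoR was higher by 1.18 (SE 0.10) and eGFP lower (-2.44, SE 0.21). The only other of the 27 vector, tag and reporter probes called was that for zebrafish Alk7 (-0.26, adjusted p = 0.0227; 0.041 without between-array normalization), whose call ended without replicates 1 or 4 of the MDA-MB-231 or 1 or 2 of the PC14 arrays (adjusted p 0.0608 to 0.0897). SV40 antigen probes were at background in both groups and not called by limma (0 at an unadjusted p under 0.05). Among ribosomal probes only the last 18S probe was called (-1.20, SE 0.09), and among mitochondrial probes only ND2 (-0.42, adjusted p = 0.015; -0.03, adjusted p = 0.949, under median scaling and 0.072 without between-array normalization). NM_009735.2 (-0.33) and NM_007393.1 (-0.28) were called lower, and both turned sign under median scaling (0.13 and 0.151). The first call ended without replicate 4 of the MDA-MB-231 or replicate 2 of the PC14 arrays (adjusted p = 0.0638 and 0.0644), and the second without replicates 2 or 4 of the MDA-MB-231 or 1, 2 or 3 of the PC14 arrays (adjusted p 0.0545 to 0.1). The immune receptor probes IGKV1-99 and TRAV6-1 were lower by at most 1.26-fold, calls that ended under median scaling (adjusted p = 0.436 and 0.113), the first with its sign turned without between-array normalization (0.021).

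**Figure D3:**
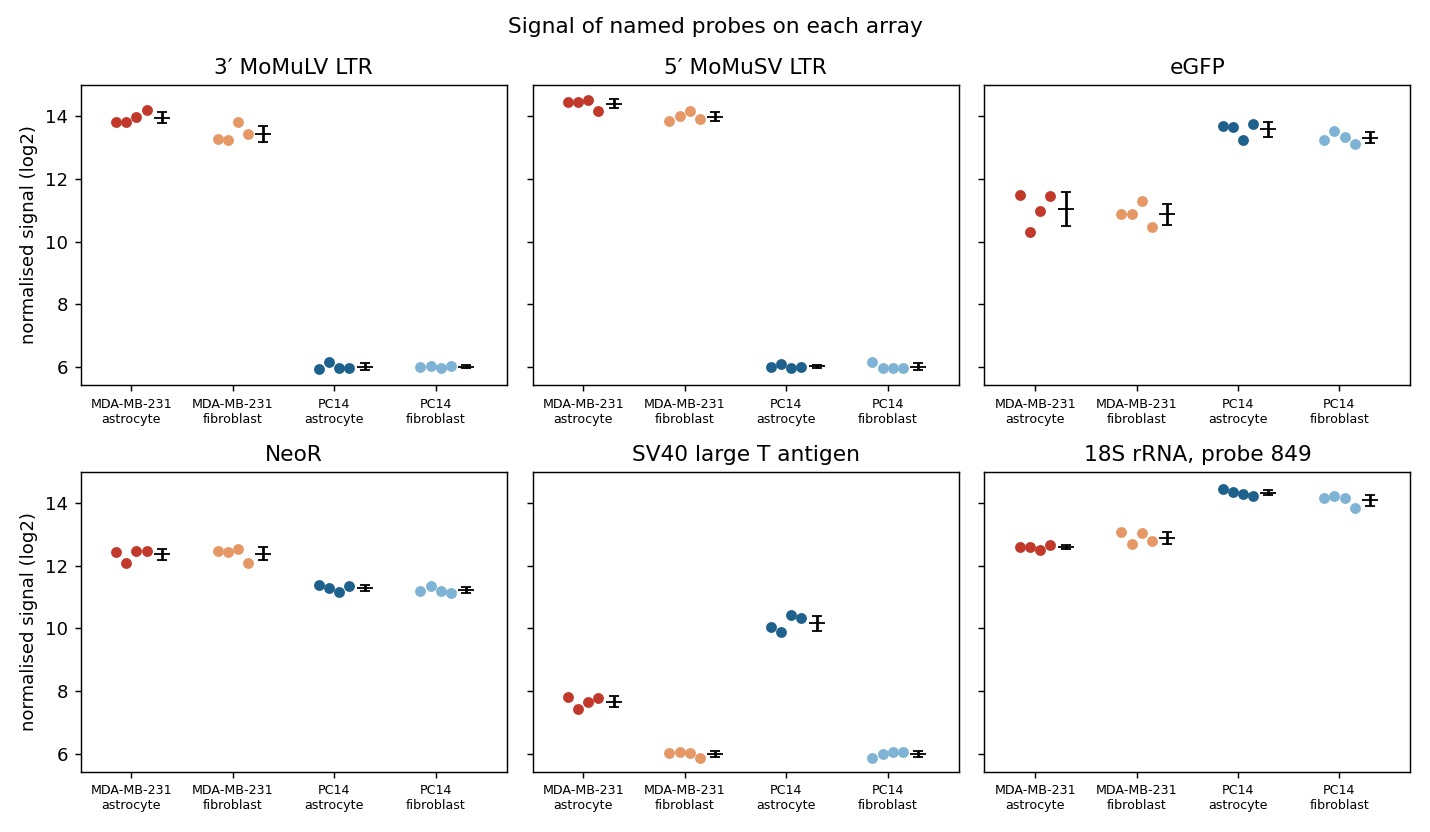
Normalised log2 signal of 6 named probes on each of the 16 arrays, by group, with mean ± SD of 4 arrays as bars. The LTR probes lie near 14 with MDA-MB-231 (means 13.45 to 14.41) and near 6 with PC14 (at most 6.01), and SV40 large T antigen is highest with PC14 and astrocytes (mean 10.17).

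With fibroblasts, 7206 features were called, 3542 higher and 3664 lower with MDA-MB-231, and 377 differed at least 2-fold (208 higher, 169 lower). Median scaling gave 8502 higher and 694 lower (at 2-fold 1410 features, 1362 higher), and no between-array normalization 11001 and 178 (at 2-fold 2022 features, 1980 higher), with a median shift of 0.116. An offset of 16 gave 584 features at 2-fold. The feature scl49743.39.1_15-S was higher with MDA-MB-231 (log2 signal 12.33 ± 0.14 against 7.21 ± 0.16) and scl31343.5.1_35-S at least 16.5-fold higher. GI_6715563-S was again lower (7.63 ± 0.19 against 14.36 ± 0.13), and scl017276.1_218-S was at least 18-fold lower. Tumour line and any batch of these arrays cannot be told apart, since the files and labels name no slide or scan.

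The tumour-line differences were also shared in part between partners. At 2-fold, 41 features were higher and 78 lower with MDA-MB-231 in both co-cultures, and 18 were opposite. Independent lists over all features would share 1.009 and 1.963, numbers that are again too low, as every 2-fold call came from features above background. Among all calls, 1051 were higher and 1323 lower in both and 936 opposite. The log2 differences correlated across features with r = 0.355 and rho = 0.26. The number called in the same direction was 2374, against 4372 (4157 higher, 215 lower) with median scaling and 5318 (5225 higher, 93 lower) without between-array normalization.

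The interaction asks whether the astrocyte minus fibroblast difference itself differed between tumour lines. SV40 large T antigen gave a difference of -2.52 (SE 0.14, limma adjusted p = 2.45e-10) and the common probe of -2.19 (SE 0.14), so that the astrocyte signal exceeded the fibroblast signal by less with MDA-MB-231 than with PC14. Both probes lay at background in both fibroblast groups, so these values repeat the tumour-line differences with astrocytes (-2.51 and -2.26). All 3 retroviral probes had positive differences, 0.52 for the 3′ LTR, 0.42 for the 5′ LTR and 0.55 for the packaging signal, at background in both PC14 groups. The calls of both LTR probes ended under cyclic loess, median scaling and no between-array normalization (adjusted p 0.163 to 0.54) and with an offset of 16, that of the packaging signal without between-array normalization (adjusted p = 0.0816), and that of the 3′ LTR without replicate 1 or 2 of MDA-MB-231 with fibroblasts (adjusted p = 0.0533 and 0.0557). NM_009735.2 (-0.79, adjusted p = 2e-04) and NM_009438.3 (0.67, adjusted p = 0.000519) also differed, as did the second probe of NM_019639.2 (-0.37), the last 18S probe (-0.55), NM_013551.1 (0.85) and IGKV4-79, which lay below background on all 16 arrays. All of these but NM_009735.2 lost their calls under median scaling (adjusted p 0.0944 to 0.648), and NM_009735.2 without between-array normalization (-0.77, adjusted p = 0.101). The NM_019639.2 call also ended without replicates 2 or 3 of PC14 with astrocytes or 3 of PC14 with fibroblasts (adjusted p 0.0508 to 0.0549). For NM_013551.1 it ended without replicates 2 or 4 of MDA-MB-231 with astrocytes, any of MDA-MB-231 with fibroblasts, 1, 2 or 3 of PC14 with astrocytes or 4 of PC14 with fibroblasts (adjusted p 0.0503 to 0.0855). For IGKV4-79 it ended without 3 or 4 of either astrocyte group, any of MDA-MB-231 with fibroblasts, or 1, 2 or 4 of PC14 with fibroblasts (adjusted p 0.0542 to 0.103). Limma called no mitochondrial probe (1 at an unadjusted p under 0.05) and no vector, tag or reporter probe (0 at an unadjusted p under 0.05).

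In all, 5752 features were called in the interaction, 2849 higher and 2903 lower, and 947 at 2-fold (335 higher, 612 lower). Of the 5752, 5631 were also called between partners with at least 1 tumour line, and 582 were called with both lines in opposite directions. Median scaling called 3293 features (1079 higher, 2214 lower; at 2-fold 242 higher, 770 lower) and no between-array normalization 2064 (626 higher, 1438 lower; at 2-fold 215 higher, 724 lower). The feature scl017313.2_5-S was higher with astrocytes for MDA-MB-231 (11.27 ± 0.40 against 7.20 ± 0.06) and lower for PC14 (7.85 ± 0.09 against 9.19 ± 0.22). The feature scl013717.1_13-S reached 11.52 ± 0.25 only with PC14 and fibroblasts and averaged at most 7.15 in the other groups. GI_40254488-S (11.06 ± 0.16) and scl24120.2_589-S (11.72 ± 0.30) were bright with PC14 and astrocytes and averaged at most 6.56 elsewhere.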

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

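The tests of the LTR signal, both tests of the SV40 signal and the other scalings of the human RNA test were chosen after results were seen; the others were written beforehand.

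Retroviral LTR probes were bright in all 8 MDA-MB-231 co-cultures and at background with PC14. Endogenous retroviral RNA that the mouse cells make with either tumour line is argued against by the pattern itself, as 0 of 16 pairs of LTR probe and array lay above background with PC14. That count restates the pattern and is not separate support. RNA made only beside MDA-MB-231 was not tested. Brighter arrays are argued against too: over the 46583 other features the raw log2 ratio of MDA-MB-231 to PC14 means had a 99th percentile of at most 1.45, against 8.06 to 8.83 for the LTR probes. A batch that follows the tumour line cannot be told apart from it. A sequence carried by the tumour cells alone stays open: the LTR probes' astrocyte minus fibroblast difference exceeded that of NeoR by 0.495 (SE 0.137, 3.61 standard errors), past the bound set for counting against it. That bound takes NeoR as a marker of the cells that carry the LTR. NeoR and eGFP lay above background on all 4 arrays of each group, so which cells carried them is not known. A comparison with eGFP, required only after the NeoR value was seen, gave 0.289 (SE 0.30, 0.964 standard errors), and since both comparisons assume that LTR and marker RNA vary together, neither decides.

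SV40 large T antigen was lower with MDA-MB-231 than with PC14 in the astrocyte co-cultures. Without between-array normalization the difference was -1.96, so the normalization does not account for it. A smaller share of astrocyte RNA as the whole cause stays open, though values count against it. It would leave each astrocyte feature the same share of its signal above the fibroblast level as large T kept. Over 323 features at least 4-fold higher with astrocytes with PC14, a choice that favours lower values with MDA-MB-231, this needs a median difference of -1.955. The median was -0.655, 275 fell by less than needed, 60 were called higher and 203 lower with MDA-MB-231, and 24 were as low as large T. The median shortfall of 1.354 did not exceed its interquartile range (1.425). Under median scaling and without normalization it did (1.401 against 1.342, and 1.40 against 1.341; medians -0.087 and 0.011), but not for features at least 8-fold higher under any of the 3 scalings (1.509 against 1.681, 1.621 against 1.677 and 1.56 against 1.666). The lower quartile of the shortfall was positive for the 4-fold and the 8-fold set under all 3 scalings (0.564 to 0.701). The set planned at first, 4-fold higher in both lines, leaves out features that fell and decides nothing, and more than 1 other form of this test was tried. A smaller share as part of the cause stays open. So does an effect of the tumour line on this transcript, or astrocytes of a different preparation, which was not tested.

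Features called at 2-fold between tumour lines could come from human RNA binding to mouse probes, which would add alike to both co-cultures if the tumour cells made the same RNA in the same share with both partners. Only 24.4% of the 767 features in the astrocyte co-cultures (95% exact binomial interval 21.4 to 27.6) and 41.6% of the 377 in the fibroblast co-cultures (36.6 to 46.8) had a linear difference of the same sign and 0.5 to 2 times as large with the other partner, below the 50% written as the limit. The intervals treat features as independent, which features on the same arrays are not. They do not measure the spread between cultures. With the 2-fold sets and signals of median scaling the shares were 31.8% and 31.6%, and without between-array normalization 41.5% and 42.8% (highest upper limit 45). Human RNA that adds alike does not account for either set under these 3 scalings. Human RNA that differs by partner was not tested and stays open. So does human RNA that adds alike for the features that were alike, among them 113 of the 169 that were lower with MDA-MB-231 in the fibroblast co-cultures.

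For all 10 counts of calls, few or no other splits of the same arrays called as many features. The other splits mix arrays of groups that differ, and the replicates may be technical. The splits therefore do not exclude chance differences between cultures. For each of the 4 contrasts of 4 against 4 arrays, 1 of 35 splits, the real one, called as many features, both in all and at 2-fold. The real counts of 10333, 9477, 8142 and 7206 stand against at most 0, 2, 0 and 39 in other splits, and the 2-fold counts of 1995, 1756, 767 and 377 against 0. For the interaction, 1 of 100 drawn splits reached 5752 (highest other 4823) and 2 reached 947 at 2-fold (highest other 1082). The split with 4823 and 1082 kept all astrocyte labels and exchanged 6 of the 8 fibroblast labels, which turns the interaction into the tumour-line difference with astrocytes plus 0.5 times that with fibroblasts, on a larger scale than a mean of them. Such splits hold tumour-line differences, so they do not decide whether chance accounts for the interaction counts.

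The astrocyte minus fibroblast difference itself differed between tumour lines for 5752 features. Among named probes it did so for SV40 large T antigen (-2.516), the common SV40 probe (-2.19), the last 18S probe (-0.546), the 3′ LTR (0.52), the 5′ LTR (0.423), the packaging signal (0.553), the second probe of NM_019639.2 (-0.369), NM_009735.2 (-0.788), NM_009438.3 (0.673), NM_013551.1 (0.848) and IGKV4-79 (-0.316). The SV40 probes lay at background in both fibroblast groups, so their values repeat the tumour-line differences with astrocytes (-2.512 and -2.262). The retroviral probes lay at background in both PC14 groups, so theirs repeat the partner differences with MDA-MB-231. Among the probes listed, the SV40 calls alone kept their calls under every alternative run. Without between-array normalization the other 9 calls ended (adjusted p 0.0816 to 0.788), and under median scaling all of these 9 but the packaging signal and NM_009735.2 (adjusted p 0.0944 to 0.648). With arrays left out, the 3′ LTR call ended without replicate 1 or 2 of MDA-MB-231 with fibroblasts (adjusted p = 0.0533 and 0.0557), and that of the second probe of NM_019639.2 without replicates 2 or 3 of PC14 with astrocytes or 3 of PC14 with fibroblasts (adjusted p 0.0508 to 0.0549). The NM_013551.1 call ended without replicates 2 or 4 of MDA-MB-231 with astrocytes, any of MDA-MB-231 with fibroblasts, 1, 2 or 3 of PC14 with astrocytes or 4 of PC14 with fibroblasts (adjusted p 0.0503 to 0.0855). The IGKV4-79 probe, below background on all 16 arrays, lost its call without 3 or 4 of either astrocyte group, any of MDA-MB-231 with fibroblasts, or 1, 2 or 4 of PC14 with fibroblasts (adjusted p 0.0542 to 0.103).

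An array stood far from the other 3 of its group in 9 of 136 groups tested, where chance would give about 6.8. The 5′ LTR was 6.156 on replicate 1 of PC14 with fibroblasts (others 5.946 to 5.967), and the second probe of NM_019639.2 13.616 on replicate 4 of MDA-MB-231 with astrocytes (others 13.68). NeoR was 12.088 on replicate 2 of MDA-MB-231 with astrocytes (others 12.431 to 12.468), an array that enters the NeoR comparison of the LTR signal. SV40 large T antigen was 5.852 on replicate 4 of MDA-MB-231 with fibroblasts (others 6.023 to 6.035). Near background, IGHV1S129 was 6.085 and TRAV5-1 6.034 on replicates 1 and 3 of MDA-MB-231 with astrocytes, TRGV4 6.33 on replicate 1 of MDA-MB-231 with fibroblasts, and TRBV12-2 6.743 on replicate 1 of PC14 with astrocytes. The median raw signal was 69.25 on replicate 4 of PC14 with astrocytes (others 53.96 to 56).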

How the results depend on the processing

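The fit on arrays 1 to 3 and the filter on features above background were chosen after the data were seen. With each array left out, no count moved by over 1.5 times: 9630 to 10513 (astrocyte minus fibroblast with MDA-MB-231), 8687 to 9528 (with PC14), 7051 to 8524 and 5654 to 7704 (tumour lines with astrocytes and with fibroblasts) and 5238 to 5858 (interaction). At 2-fold the ranges were 1918 to 2015, 1725 to 1802, 732 to 804, 353 to 419 and 885 to 987, and for shared changes 5422 to 5614 (partners) and 2031 to 2544 (tumour lines). Median scaling moved the PC14 partner contrast to 6059, the interaction to 3293, the tumour-line 2-fold counts to 1388 and 1410, and the shared tumour-line change to 4372. Without between-array normalization the PC14 partner contrast gave 4727, the fibroblast tumour-line contrast 11179, the interaction 2064, the tumour-line 2-fold counts 1818 and 2022, and the shared changes 3031 (partners) and 5318 (tumour lines). An offset of 16 gave 584 at 2-fold for tumour lines with fibroblasts. The cause was not tested. No other alternative run moved these counts by over 1.5 times. The astrocyte minus fibroblast contrast with MDA-MB-231 ranged from 7053 to 11267.

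The labels do not say that replicate numbers pair the samples, and the correlations did not meet the rule used here, a value over 0.1 for every same-numbered pair: deviations of same-numbered arrays correlated at 0.046 to 0.16, 0.064 to 0.11, 0.079 to 0.21 and 0.28 to 0.43 for numbers 1 to 4. All of these correlations were positive and highest for number 4, so the values go with a shared effect of the number. The main model leaves this effect out. Pairs with different numbers correlated at -0.26 to 0.18 (median -0.059), and 10 of 16 arrays correlated best with their own number. This rests on the data and not on the design. The replicate block raised every count, from 10333, 9477, 8142, 7206 and 5752 to 11267, 10600, 9681, 8930 and 6933 in the order of the contrasts, and 1 of 89 named calls was lost. With arrays 1 to 3 alone they were 9826, 9231, 7953, 6893 and 5503.

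Over named probes, 868 of 956 values from the alternatives chosen at the start, 1330 of 1424 from left-out arrays and 162 of 169 from added ones kept direction and call. The sign turned in 15, the cause not tested. For tumour lines with astrocytes these were, under median scaling and without between-array normalization, the middle 18S probe (0.012, 0.109), the second probe of NM_019639.2 (0.099, 0.196), ND2 (0.246, 0.344) and ND5 (0.045, 0.142). For tumour lines with fibroblasts they were NM_009735.2 (0.13, 0.23) and NM_007393.1 (0.151, 0.252), and without normalization also IGKV1-99 (0.021), zebrafish Alk7 (0.041) and ND2 (0.072). LTR, SV40 large T, eGFP and NeoR differences between tumour lines with astrocytes kept their calls under every alternative run. No slide block or gene list alternative was run, and a fit of only the groups compared gives no separate interaction. Signal over background limits dim features: 28650 lay at or below background on all 16 arrays.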

Other observations

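Some probes of 35 numbered families, whose identities the files do not give, differed between tumour lines. The families have 146 probes and a further 139 marked rc, of which 17 and 12 lay above background on at least 4 arrays. With astrocytes, limma called 11 of the 146 higher and 4 lower with MDA-MB-231, and 8 and 3 of the 139. Of all features, 17.5% were called in that contrast. Of the 146 probes, 7 differed at least 2-fold between tumour lines with astrocytes and 9 with fibroblasts by limma, with log2 differences over all members from -0.84 to 6.94 and from -1.40 to 6.42. Of the rc kind 7 and 6 did, with differences from -1.78 to 2.39 and from -1.92 to 1.79. Between partners no probe of either kind was called at 2-fold with either tumour line. The probe with the largest difference had a raw signal of 25350 ± 1759 with MDA-MB-231 and astrocytes against 169.6 ± 71.3 with PC14 and astrocytes (SD, n = 4). The rc probe with the most negative difference had 77.86 ± 10.4 against 221 ± 41.7. These probes were singled out after their values were seen.

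Some features were detected with one kind of partner alone. Counting raw signals above background, 407 features were detected on all 8 astrocyte arrays and on none of the 8 fibroblast arrays, and 178 the other way round. Between tumour lines the counts were smaller: 46 features on all 8 MDA-MB-231 arrays and no PC14 array, and 16 the reverse. For a single group against the other 12 arrays there were 142 features for PC14 with astrocytes, 95 for MDA-MB-231 with fibroblasts, 77 for MDA-MB-231 with astrocytes and 1 for PC14 with fibroblasts. These counts rest on the background limit and were not tested.

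The 3 18S ribosomal RNA probes were not all called between tumour lines, and differences between probes were not tested. The last was called lower with MDA-MB-231 with both partners, and the middle with astrocytes (-0.54, but 0.012 under median scaling). The first had normalised log2 means of 14.61 ± 0.38 and 14.67 ± 0.09 with astrocytes for MDA-MB-231 and PC14 (SD, n = 4) and was not called. Its raw means there, 26260 and 24340, lay near the array maxima (31860 to 38137), where a difference may not show. The CDKN2A p16 probe lay at or below background on all 16 arrays, so its small call between tumour lines with astrocytes (-0.205) has no measured level behind it, and that call ended without replicate 4 of MDA-MB-231 with astrocytes (adjusted p = 0.0614), without between-array normalization (adjusted p = 0.295) and on the arrays numbered 1 to 3 alone (adjusted p = 0.0778).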
